A study of Drosophila melanogaster with 12 samples.

How the data were processed

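RNA sequencing libraries were made from sorted cells of the Drosophila melanogaster optic lobe. Per the labels, driver lines for each cell type were crossed to a nuclear red fluorescent reporter, brains of adults aged 3 days were dissociated and labelled cells were sorted by fluorescence. Total RNA was turned into full-length cDNA with SMART-Seq v4, made into Nextera XT libraries and sequenced as paired reads of 100 bases on an Illumina HiSeq. The labels give 3 libraries each of T4 neurons, Pm2 neurons, neurons (Elav driver, a control) and glia (Repo driver, a control), with 3 libraries pooled per sequencing lane. Which libraries shared a lane is not stated, so an effect of lane could not be tested. Per the submitters' processing notes, the authors used Trimmomatic 0.32, STAR 2.5.2 and HTSeq 0.6.1 with the BDGP6 build, whose release is not given, and no settings are stated.

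The deposited table holds whole-number counts for 16272 gene names in 12 columns, although its name calls the values normalized and no header says how. Ratios between libraries had medians of 0.793 to 1.23. A scan for whole numbers made by rounding scaled counts gave a gain of at most 6.18, against at least 169 in simulated scaled counts. The values were therefore analysed as counts; an adjustment made gene by gene cannot be excluded from the values. Columns named for the Elav driver were assigned to the group of neurons but not to single sample titles, whose numbers differ, so the numbers of the neuron replicates here are column numbers. Of the gene names, 11996 matched a current symbol and 4085 a synonym in the Ensembl annotation of the BDGP6 assembly, from which coordinates were taken; 191 matched none.

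Genes with at least 10 counts in at least 3 of the 12 libraries were tested, 10528 genes. Libraries were scaled by trimmed mean of M values (TMM) and all 12 were fitted together with group means in edgeR 4.0.16 (quasi-likelihood F test, two-sided) under R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested. Standard errors of log2 differences were computed from the difference and its F value. Scaled levels (CPM) are counts per 1000000 counts of the TMM-adjusted library total. The comparisons were glia with neurons, T4 with neurons, Pm2 with neurons and T4 with Pm2; T4 with glia and Pm2 with glia served to find enriched genes, those called higher in a neuron type than in each of the other 3 populations. The use of this test for counts, the comparisons, 34 gene lists and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 5 higher and 5 lower called genes with the largest log2 difference, a mean of at least 100 counts in the higher group and all 3 libraries of one group above the other 3, an order that chance gives for 10% of genes. It adds up to 4 members of each list by adjusted p, a fixed set of marker genes, and the 8 genes of each enriched set with the largest smallest difference.

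Lists with at least 3 tested members were tested in limma 3.58.1 with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with counts of members called over all genes and adjusted over the list alone. The lists cover pan-neuronal, glial and transmitter genes, receptors, channels, cell-surface families, transcription factors, metabolism, phagocytosis, stress and immediate early genes, antimicrobial peptides, ribosomal, mitochondrial and sex-related genes, and markers of photoreceptors, haemocytes, fat body, muscle, trachea and Kenyon cells. Some genes are in more than 1 list. In 16 list comparisons, none of them called, the median, the mean and the camera direction differed in sign. Camera with an estimated correlation and fry, whose tests ask whether a list's genes move one way or in either direction, were alternatives. Replicate numbers of T4, Pm2 and glia were not treated as pairs, since libraries with the same number did not deviate together. Their deviations of log2 CPM from the population mean of each gene had correlations between -0.029 and 0.025.

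Library totals were 35012892 to 57811629 counts. Replicates varied beyond counting error, with chi-square per degree of freedom between 18.7 and 320. On simulated data built for each of the 4 comparisons, edgeR recovered 4.48% to 11.9% of 1.5-fold, 29.9% to 40.3% of 2-fold and 60.6% to 77.3% of 4-fold changes, with 0% to 5% of its calls false. Each set changed 66 or 67 genes per fold step among 9747 to 10106 genes, with spread taken from the edgeR fit. Far more genes were called in the real comparisons, so these rates do not give their power. On the same data 21.1% to 24.8% of DESeq2 calls and 4.69% to 33.6% of limma calls were false. The limma fits had no scaling and the spread came from edgeR, so these rates do not rank the tools. Ratio intervals are 95% counting intervals. Alternatives were median-of-ratios scaling, no filter, a filter at 100 counts, limma-trend on log2 values with pseudocounts of 0.1 and 5, quantile normalization, limma without a trend, library weights, DESeq2 1.42.0, only the 6 libraries compared, a replicate block, a 2-fold threshold and leaving out each library. Scaling by library total, the counts as deposited without scaling, and limma-trend on log2(value + 1) as deposited were chosen after seeing the data. Among these alternatives, all limma fits except quantile normalization used counts that were not scaled between libraries. Overlaps, permutations and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the comparisons.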

Results

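RNA was sequenced from 4 cell populations sorted by fluorescence from the optic lobe of Drosophila melanogaster adults aged 3 days. T4 and Pm2 are single neuron types of the optic lobe. T4 neurons are columnar cells of the ON motion pathway, and Pm2 neurons are cells of the proximal medulla. The other populations were all neurons, sorted with the Elav driver, and glia, sorted with the Repo driver, and the series names both as controls. Each population had 3 libraries, 12 in total, and the labels do not say whether the libraries came from separate animals or pools. The p-values therefore measure the spread between libraries. Per the labels each cell type had its own driver line, so differences between populations cannot be told apart from differences between driver lines.

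Library totals were 44522117 to 48441795 counts in T4, 51397068 to 57811629 in Pm2, 35012892 to 44502669 in neurons and 49893609 to 57631228 in glia. Between 9706 and 12742 genes had a count in a library. Levels are counts per 1000000 scaled counts (CPM), given as mean ± SD with n = 3. For a gene with no count in a population, 3 counts over its 3 libraries set the upper limit, which lay between 0.0186 CPM in Pm2 and 0.0239 CPM in neurons. These limits, and the intervals given with ratios, cover counting error only. The gene Msr-110, picked after its values were seen, held 6.43% to 9.14% of all counts in the glia libraries, and the 10 most abundant genes held 18.9% to 22.0% there, against 6.82% to 11.04% in the other libraries. Genes with rRNA in their name, which include mitochondrial ones, held 0.615%, 1.55% and 2.61% of the counts in the 3 neuron libraries. In T4 they held 0.377% to 0.383%. In neurons replicate 3 the mitochondrial gene mt:lrRNA alone held 2.60% of the counts.

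Libraries of one population lay together. The first principal component held 61.55% of the variance and separated glia from the neuron populations, and the second held 17.89% and separated Pm2 from the rest. Across genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.970 to 0.972 within T4, 0.980 to 0.982 within Pm2, 0.969 to 0.977 within neurons and 0.935 to 0.943 within glia. Correlations between T4 and neuron libraries were 0.909 to 0.926, and those between Pm2 and neuron libraries were 0.862 to 0.869.

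**Figure D1:**
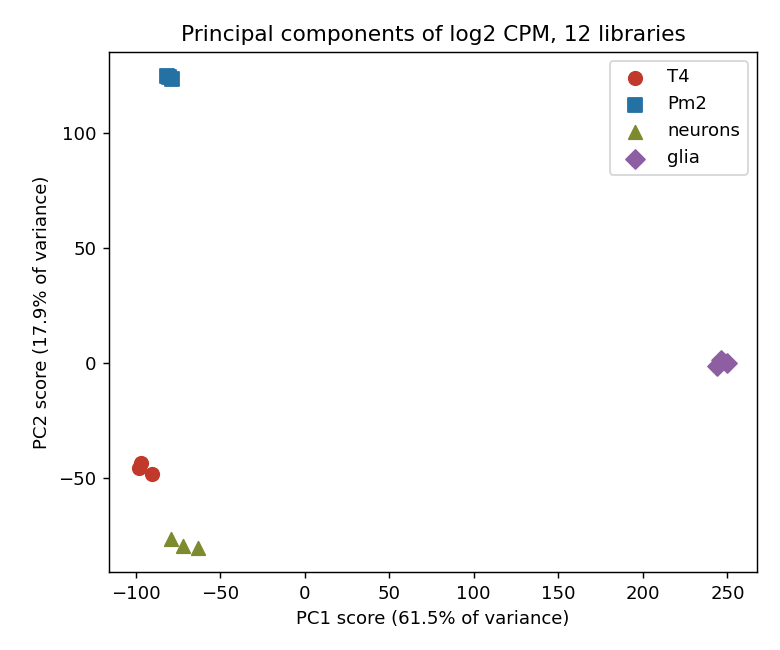
Principal components of the 12 libraries computed from log2 CPM of the 10528 tested genes; each point is a library, coloured by population. The horizontal axis holds 61.55% of the variance and the vertical axis 17.89%, and the 3 glia libraries lie apart on the horizontal axis.

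The comparison of glia with neurons asked how the control populations differed. Most pan-glial genes were higher in glia. The glial transcription factor repo (3R, 18236192 to 18239602, FBgn0011701, BDGP6 assembly) stood at 3427 ± 410 CPM in glia and 0.845 ± 0.350 in neurons (n = 3 each; edgeR adjusted p = 1.34e-06). The glutamine synthetase gene Gs2 stood at 11228 ± 1240 CPM against 71.9 ± 8.3, and the GABA transporter gene CG1732 (Gat) at 6967 ± 1143 against 12.4 ± 1.3. In neurons, the synaptic vesicle gene nSyb (3L, 1630348 to 1637752, FBgn0013342) stood at 2997 ± 85 CPM against 45.8 ± 4.3 in glia, a log2 difference of -6.03 ± 0.11 (SE; edgeR adjusted p = 4.06e-11). The active-zone gene brp stood at 1134 ± 86 CPM in neurons and 18.3 ± 8.1 in glia.

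All 18 pan-neuronal genes were lower in glia (18 adjusted over the list alone, camera adjusted p = 1.64e-31). The RNA-binding protein gene elav differed least of the 18, with 138 ± 24 CPM in glia and 641 ± 7.6 in neurons (log2 -2.21 ± 0.13; edgeR adjusted p = 4.37e-08). Of 19 pan-glial genes, 18 were higher (18 adjusted over the list alone, camera adjusted p = 3.82e-08), among them nrv2 at 6466 ± 1786 CPM against 81.7 ± 10.8. Of 12 astrocyte and ensheathing glia genes, 11 were higher (11 adjusted over the list alone, camera adjusted p = 1.49e-06), and alrm stood at 6551 ± 296 CPM against 14.6 ± 1.4. All 5 tested cortex glia genes were higher, including Cyp4g15 at 1926 CPM against 1.65 (5 adjusted over the list alone, camera adjusted p = 0.0207, and adjusted p = 0.0729 with an estimated correlation). Surface glia and barrier junction genes were higher in 9 of 16 cases and lower in 1 (the same counts adjusted over the list alone, camera adjusted p = 0.00628). In this list moody, a receptor of the blood-brain barrier, stood at 229 ± 37 CPM against 2.06 ± 0.87.

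Transmitter receptor and channel genes were lower in glia. This held for all 9 nicotinic acetylcholine receptor genes (9 adjusted over the list alone, camera adjusted p = 2.78e-09), such as nAChRbeta1 at 10.1 CPM against 1108. Of 16 GABA and glutamate receptor genes, 15 were lower and 1 was higher (15 and 1 adjusted over the list alone, camera adjusted p = 8.45e-09), and Rdl stood at 27.3 CPM against 2262. Aminergic and muscarinic receptor genes were lower in 19 of 21 cases (20 adjusted over the list alone, camera adjusted p = 7.91e-08). Potassium and calcium channel genes were lower in 16 of 19 cases and higher in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 5.27e-19). The cell-surface families that mark synaptic partners were lower too: 29 of 31 dpr and DIP genes (29 adjusted over the list alone, camera adjusted p = 2.68e-06) and 20 of 21 beat and side genes, with 1 higher (20 and 1 adjusted over the list alone, camera adjusted p = 1.83e-09). The cholinergic genes Cha, VAChT and CG7708 (ChT) were all lower (3 of 3 adjusted over the list alone, camera adjusted p = 0.0185, and adjusted p = 0.168 with an estimated correlation). Gad1, VGAT and VGlut, whose lists were too short for a set test, were lower as well, at 42.6, 3.78 and 10.3 CPM in glia against 1698, 258 and 924 in neurons.

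Among 55 optic lobe identity transcription factors, 42 were lower and 7 higher in glia (42 and 7 adjusted over the list alone, camera adjusted p = 0.00918). The higher ones included pros at 35732 ± 8264 CPM against 1046 ± 179 (log2 5.09 ± 0.23) and zfh2 at 1189 ± 214 against 58.8 ± 9.7. All 8 T4 and T5 transcription factors were lower (8 adjusted over the list alone, camera adjusted p = 0.00171). Of 10 phagocytosis genes, 8 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00157), with mbc at 3182 ± 781 CPM against 30.5 ± 1.9 and the adaptor ced-6 at 361 ± 49 against 2.91 ± 0.52. Ribosomal protein genes were higher in 72 of 86 cases and lower in 1 (73 and 1 adjusted over the list alone, camera adjusted p = 1.49e-06, and adjusted p = 0.597 with an estimated correlation). The list median was log2 1.09, and RpL22 lay far above it, at 535 ± 83 CPM against 31.6 ± 3.3. Mushroom body Kenyon cell genes were lower in 6 of 8 cases (7 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.104 with an estimated correlation). Among the largest differences, the cytochrome P450 gene Cyp6a20 stood at 216 ± 35 CPM in glia with no count in neurons, at least 9073-fold higher. The transcription factor gene ken stood at 1039 ± 104 CPM against 0.0159 ± 0.0140, a ratio with a 95% counting interval from 18082 to 539348. The cell-surface gene dpr2 had no count in glia and stood at 102 ± 6.1 CPM in neurons, at least 4637-fold lower in glia.

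edgeR called 7236 of 10528 genes between glia and neurons, 3252 higher and 3984 lower in glia, and 5715 of them by at least 2-fold. Scaling by library total gave 2674 higher and 4657 lower. The camera test called 17 lists, of which 13 were called with an estimated correlation. Splits that mixed glia and neuron libraries called 13 to 20 lists, so the number of lists called does not set the real groups apart.

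**Figure D2:**
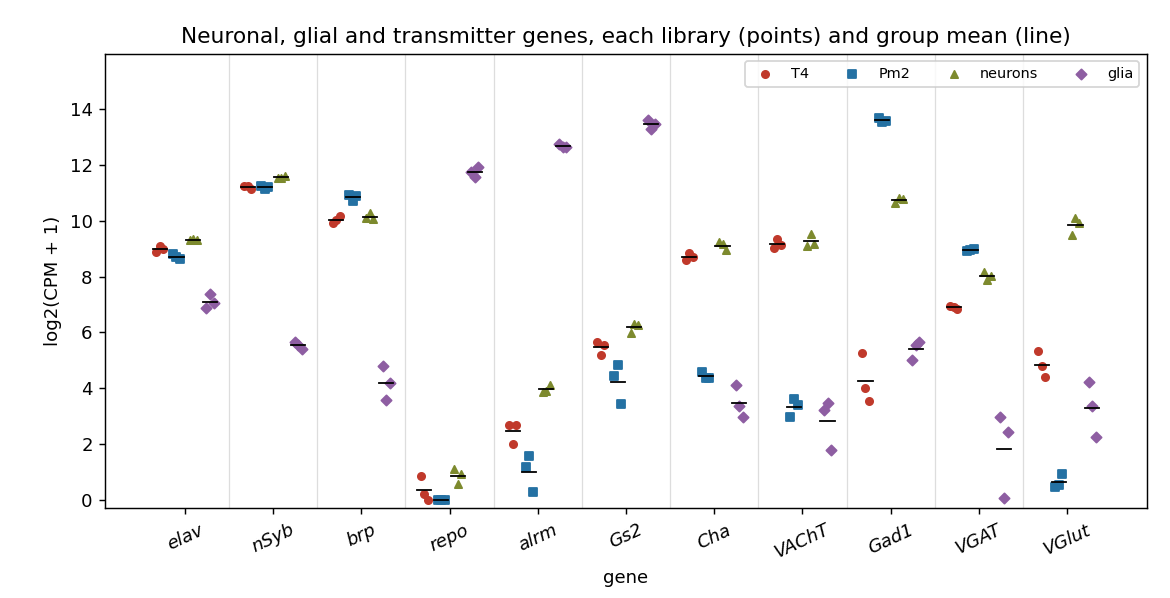
Levels of 11 neuronal, glial and transmitter genes in each library as log2(CPM + 1); points are libraries, black lines the mean of the 3 log2 values, and colours the populations. Gad1 was highest in Pm2 at 12445 CPM and repo in glia at 3427 CPM; elav in glia, at 138 CPM, lay nearer to its neuron level than nSyb or brp did.

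T4 was set against all neurons to ask which genes set this neuron type apart from the mixed population. The Elav sort can itself hold T4 and Pm2 cells, so each type is compared with a mixture that can include it. Their share in that mixture is not known. Some transcription factor genes were higher in T4, while more of the optic lobe identity factors were lower. Lim1 (X, 8756539 to 8805804, FBgn0026411), a LIM-homeodomain factor, stood at 819 ± 73 CPM in T4 and 115.1 ± 16.3 in neurons (log2 2.83 ± 0.23; n = 3 each; edgeR adjusted p = 1.55e-05). The Sox factor gene Sox102F stood at 865 ± 72 CPM against 228 ± 23.5, SoxN (2L, 8825645 to 8829670, FBgn0029123) at 1383 ± 70 against 350 ± 14, and the POU factor gene acj6 at 605 ± 56 against 125 ± 16. Gad1, which encodes the enzyme that makes GABA, was lower in T4, at 20.9 ± 14.2 CPM against 1698 ± 111. So was the vesicular glutamate transporter gene VGlut, at 28.7 ± 9.7 against 924 ± 184. The vesicular GABA transporter gene VGAT did not pass the test, at 118 ± 4.5 CPM in T4 and 258 ± 25 in neurons (log2 -1.13 ± 0.73; edgeR adjusted p = 0.297; over its alternatives from 2.73e-05, with only the 6 libraries compared, to 0.718). The cholinergic genes did not pass the test, with VAChT (3R, 18705501 to 18718916, FBgn0270928) at 573 ± 71 CPM in T4 and 616 ± 100 in neurons (edgeR adjusted p = 0.884) and Cha at 420 ± 42 against 553 ± 55 (edgeR adjusted p = 0.272; over its alternatives from 0.0203, with only the 6 libraries compared, to 0.828).

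Of 8 T4 and T5 transcription factors, 4 were higher in T4 (5 adjusted over the list alone) and none was called lower (camera adjusted p = 0.00694, and adjusted p = 0.161 with an estimated correlation). These 4 were Sox102F, TfAP-2, acj6 and SoxN, with log2 differences of 1.93 ± 0.23, 1.96 ± 0.34, 2.28 ± 0.41 and 1.98 ± 0.38. The list member dac stood at 32.3 ± 8.9 CPM in T4 and 31.4 ± 11.2 in neurons (edgeR adjusted p = 0.981). Of the 55 optic lobe identity transcription factors, 34 were lower and 7 higher (34 and 8 adjusted over the list alone, camera adjusted p = 1.99e-07). Among the lower ones, ap stood at 2.67 ± 1.31 CPM against 206 ± 22, scro at 23.2 ± 8.6 against 703 ± 52 and toy at 1.62 ± 1.21 against 298 ± 37. The homeodomain genes Awh and mirr had no count in T4 and were at least 1120-fold and 1077-fold lower than in neurons.

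Neuropeptide genes were lower in T4 in 13 of 21 cases (15 adjusted over the list alone, camera adjusted p = 8.09e-06), including sNPF at 6.51 ± 2.86 CPM against 906 ± 198 and Nplp1 at 51.7 ± 14.2 against 458 ± 49.5. Beat and side genes were lower in 12 of 21 cases and higher in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 3.8e-05, and adjusted p = 0.069 with an estimated correlation). Of 31 dpr and DIP genes, 13 were lower and 2 higher (13 and 2 adjusted over the list alone, camera adjusted p = 0.0104, and adjusted p = 0.143 with an estimated correlation). The higher ones included dpr10 at 454 ± 54 CPM against 119 ± 5.1. Aminergic and muscarinic receptor genes were lower in 8 of 21 cases and higher in 1 (the same counts adjusted over the list alone, camera adjusted p = 0.0271, and adjusted p = 0.25 with an estimated correlation), with Dop2R at 1.44 ± 0.46 CPM against 132 ± 9.6. Nicotinic receptor genes were lower in 2 of 9 cases (camera adjusted p = 0.456). In limma with library weights on unscaled counts, 3 were higher and 2 lower. There the median of all genes moved by 0.323, and the list median was -0.0045 relative to all genes. Among the nicotinic receptor genes, nAChRalpha6 stood at 6.67 ± 2.39 CPM against 685 ± 24. GABA and glutamate receptor genes were lower in 7 of 16 cases and higher in 2 (camera adjusted p = 0.505). Among the higher ones CG8916, of the GABA receptor family, stood at 729 ± 65 CPM against 237 ± 39.

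Lists of stress, energy and ribosomal genes were called lower in T4 than in neurons at the preset correlation and lost the call with an estimated one. Of 13 heat-shock genes, 12 were lower (12 adjusted over the list alone, camera adjusted p = 2.09e-08, and adjusted p = 0.069 with an estimated correlation), such as Hsp26 at 4.45 ± 1.72 CPM against 89.9 ± 25.6. Of 13 mitochondrially encoded genes, 12 were lower (13 adjusted over the list alone, camera adjusted p = 1.99e-07, and adjusted p = 0.323 with an estimated correlation), with mt:CoIII at 609 ± 19 CPM against 2688 ± 515. Of 13 glycolysis genes, 9 were lower (10 adjusted over the list alone, camera adjusted p = 3.8e-05, and adjusted p = 0.206 with an estimated correlation), with Ald at 887 ± 90 CPM against 1728 ± 154. Ribosomal protein genes were lower in 18 of 86 cases and not called in 68 (13 adjusted over the list alone, camera adjusted p = 0.00694, and adjusted p = 0.767 with an estimated correlation). Markers of other cells moved as well: pan-glial genes were lower in 10 of 19 cases and higher in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00771, and adjusted p = 0.363 with an estimated correlation). Astrocyte and ensheathing glia genes were lower in 6 of 12 cases and higher in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0104, and adjusted p = 0.323 with an estimated correlation). The list median was log2 -1.22, and the glutamate transporter gene Eaat1 lay far below it, at 4.98 ± 0.98 CPM against 488 ± 136. The source of the Eaat1 RNA in neurons was not tested. Photoreceptor genes were lower in 4 of 13 cases and higher in 1 (5 and 2 adjusted over the list alone, camera adjusted p = 0.04, and adjusted p = 0.229 with an estimated correlation). Kenyon cell genes were lower in 5 of 8 cases (5 adjusted over the list alone, camera adjusted p = 0.00179, and adjusted p = 0.102 with an estimated correlation).

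Among the largest increases were the ciliary gene Tektin-C (3L, 5794405 to 5796543, FBgn0035638), at 25.02 ± 4.82 CPM in T4 and 0.241 ± 0.137 in neurons (log2 6.73 ± 0.44; edgeR adjusted p = 3.86e-06), and the adenylate cyclase gene ACXC, at 141 ± 32 against 4.02 ± 1.05 (log2 5.13 ± 0.34; edgeR adjusted p = 1.73e-05). edgeR called 2444 of 10528 genes, 913 higher and 1531 lower in T4, and 1232 of them by at least 2-fold. The balance of directions depended on scaling: the counts as deposited, without scaling, gave 1730 higher and 902 lower, and quantile normalization gave 1501 higher and 1316 lower. The camera test called 14 lists, of which optic lobe identity transcription factors and neuropeptides, 2 lists, were called with an estimated correlation.

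Pm2 was compared with all neurons to ask the same of the second neuron type. Pm2 libraries carried the transcripts of GABA synthesis and few of the other fast transmitters. Gad1 (3L, 4074077 to 4088744, FBgn0004516), which encodes the enzyme that makes GABA, stood at 12445 ± 745 CPM in Pm2 and 1698 ± 111 in neurons (log2 2.87 ± 0.38; n = 3 each; edgeR adjusted p = 0.000164). VAChT stood at 9.17 ± 2.16 CPM against 616 ± 100, Cha at 20.7 ± 2.1 against 553 ± 55, and VGlut at 0.573 ± 0.276 against 924 ± 184. The vesicular GABA transporter gene VGAT (2R, 14198478 to 14201249, FBgn0033911) did not pass the test, at 494 ± 11 CPM against 258 ± 25 (log2 0.93 ± 0.72; edgeR adjusted p = 0.348; over its alternatives from 2.03e-05, with only the 6 libraries compared, to 0.512). The 3 Pm2 libraries, at 485 to 507 CPM, all lay above the 3 neuron libraries, at 233 to 284 CPM. The glia libraries, which enter the shared spread of the main test, ranged from 0.0387 to 6.85 CPM. The 3 cholinergic genes were all lower (3 adjusted over the list alone, camera adjusted p = 1.31e-05, and adjusted p = 0.0624 with an estimated correlation).

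Of the 55 optic lobe identity transcription factors, 43 were lower and 6 higher in Pm2 (44 and 7 adjusted over the list alone, camera adjusted p = 2.86e-17). The nuclear receptor gene svp (3R, 12258737 to 12302785, FBgn0003651) stood at 302 ± 20 CPM against 33.9 ± 2.9 (log2 3.15 ± 0.77; edgeR adjusted p = 0.00839), and TfAP-2 at 294 ± 3.6 against 108 ± 14 (log2 1.44 ± 0.33; edgeR adjusted p = 0.00625). The LIM-homeodomain gene Lim3 did not pass the test, at 198 ± 7.3 CPM against 69.8 ± 2.2 (edgeR adjusted p = 0.0975; over its alternatives from 2.97e-07, with only the 6 libraries compared, to 0.258). Its Pm2 libraries, at 192 to 206 CPM, all lay above the neuron libraries, at 67.9 to 72.3 CPM, and its glia libraries ranged from 0.0228 to 2.09 CPM. Of the T4 and T5 transcription factors, 6 of 8 were lower and 2 higher (the same counts adjusted over the list alone, camera adjusted p = 0.00015, and adjusted p = 0.0624 with an estimated correlation). The eye-field gene toy stood at 0.388 ± 0.341 CPM against 298 ± 37, and Ets65A and hbn had no count in Pm2, at least 5556-fold and 4869-fold lower than in neurons.

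Of 31 dpr and DIP genes, 23 were lower and 1 higher (the same counts adjusted over the list alone, camera adjusted p = 5.5e-11), including dpr10 at 0.472 ± 0.194 CPM against 119 ± 5.1. Beat and side genes were lower in 12 of 21 cases and higher in 5 (the same counts adjusted over the list alone, camera adjusted p = 0.000774, and adjusted p = 0.0624 with an estimated correlation). GABA and glutamate receptor genes were lower in 10 of 16 cases and higher in 4 (the same counts adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.0624 with an estimated correlation). The GABA receptor gene Rdl stood at 593 ± 10 CPM against 2262 ± 288, and the NMDA receptor gene Nmdar2 at 1825 ± 77 against 281 ± 7.0 (log2 2.70 ± 0.21). Aminergic and muscarinic receptor genes were lower in 14 of 21 cases and higher in 4 (the same counts adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.229 with an estimated correlation). Nicotinic receptor genes were higher in 2 of 9 cases and lower in 2 (camera adjusted p = 0.36). Of these, nAChRalpha7 was higher at 4031 ± 155 CPM against 1305 ± 225 (log2 1.63 ± 0.24) and nAChRalpha6 lower at 0.911 ± 0.176 against 685 ± 24. Potassium and calcium channel genes were lower in 7 of 19 cases and higher in 4 (the same counts adjusted over the list alone, camera adjusted p = 0.00173, and adjusted p = 0.0624 with an estimated correlation). In limma with library weights on unscaled counts, where the median of all genes moved by 0.39, 10 of these channel genes were higher and 6 lower. Their median was then -0.0144 relative to all genes. The T-type calcium channel gene Ca-alpha1T stood at 3.51 ± 0.52 CPM against 1508 ± 75.

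Neuropeptide genes were lower in 12 of 21 cases and higher in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.0194, and adjusted p = 0.0624 with an estimated correlation). Nplp1 was higher at 1741 ± 178 CPM against 458 ± 49.5 (log2 1.93 ± 0.21), and sNPF lower at 0.537 ± 0.339 against 906 ± 198. Lipid metabolism genes were higher in 4 of 16 cases and lower in 3 (camera adjusted p = 0.359). The lipocalin gene NLaz stood at 1284 ± 73 CPM against 61.4 ± 7.4 (log2 4.39 ± 0.30) and the fatty acid synthase gene CG3523 (FASN1) at 578 ± 3.9 against 62.1 ± 8.5. The heat-shock gene Hsp70Bb (3R, 12505793 to 12508139, FBgn0013278) stood at 310 ± 13 CPM against 14.7 ± 6.2 (log2 4.40 ± 0.29; edgeR adjusted p = 7.11e-07), while its list was not called (camera adjusted p = 0.547). Glial markers were lower: 12 of 19 pan-glial genes, with 2 higher (12 and 3 adjusted over the list alone, camera adjusted p = 0.00449, and adjusted p = 0.271 with an estimated correlation). Astrocyte and ensheathing glia genes were lower in 10 of 12 cases (10 adjusted over the list alone, camera adjusted p = 1.4e-05, and adjusted p = 0.0624 with an estimated correlation). Cortex glia genes were lower in 3 of 5 cases (3 adjusted over the list alone, camera adjusted p = 0.00915, and adjusted p = 0.0624 with an estimated correlation). Photoreceptor genes were lower in 8 of 13 cases (9 adjusted over the list alone, camera adjusted p = 0.00161, and adjusted p = 0.0624 with an estimated correlation), with the diacylglycerol kinase gene rdgA at 2.79 ± 0.39 CPM against 370 ± 23.

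Among the largest increases, Tektin-C stood at 89.1 ± 4.6 CPM in Pm2 against 0.241 ± 0.137 in neurons, and the cytochrome P450 gene Cyp313a2 at 8.56 ± 1.55 CPM with no count in neurons, at least 359-fold higher. edgeR called 3749 of 10528 genes, 1637 higher and 2112 lower in Pm2, and 2244 of them by at least 2-fold. The counts as deposited, without scaling, gave 2673 higher and 1355 lower, and quantile normalization gave 2387 higher and 1824 lower. The camera test called 13 lists, of which optic lobe identity transcription factors and dpr and DIP genes, 2 lists, were called with an estimated correlation.

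**Figure D3:**
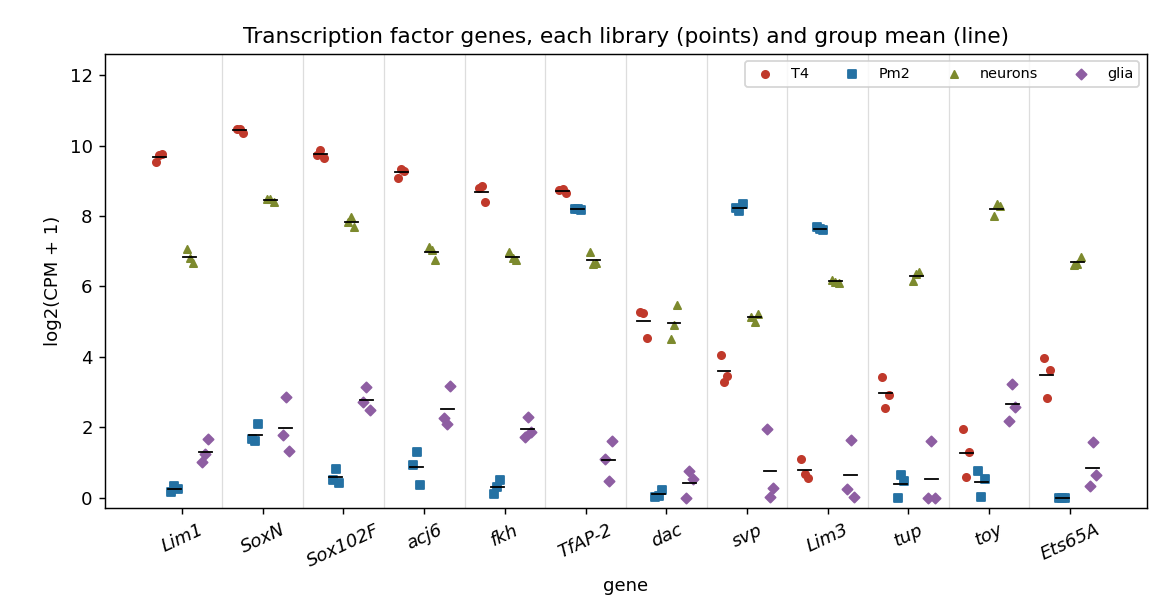
Levels of 12 transcription factor genes in each library as log2(CPM + 1); points are libraries, black lines the mean of the 3 log2 values, and colours the populations. Lim1 averaged 819 CPM in T4 and 0.187 in Pm2, and Lim3 averaged 0.744 CPM in T4 and 198 in Pm2.

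The direct comparison of T4 with Pm2 asked how the 2 single neuron types differed. They differed in transmitter genes: VAChT stood at 573 ± 71 CPM in T4 and 9.17 ± 2.16 in Pm2 (log2 5.96 ± 0.46; n = 3 each; edgeR adjusted p = 2.35e-06), and Gad1 at 20.9 ± 14.2 against 12445 ± 745 (log2 -9.21 ± 0.51; edgeR adjusted p = 1.49e-07). They also differed in transcription factors. Lim1 stood at 819 ± 73 CPM in T4 and 0.187 ± 0.063 in Pm2 (log2 12.08 ± 0.36; edgeR adjusted p = 2.7e-09), and the forkhead gene fkh at 415 ± 66 against 0.239 ± 0.172. In the other direction, svp stood at 11.4 ± 3.6 CPM in T4 and 302 ± 20 in Pm2, and Lim3 (2L, 19079256 to 19108427, FBgn0002023) at 0.744 ± 0.368 against 198 ± 7.3.

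All 3 cholinergic genes were higher in T4 (3 adjusted over the list alone, camera adjusted p = 1.18e-05, and adjusted p = 0.137 with an estimated correlation), with the choline transporter gene CG7708 (ChT) at 602 ± 114 CPM against 1.78 ± 1.03. VGAT stood at 118 ± 4.5 CPM in T4 and 494 ± 11 in Pm2, which did not pass the test (log2 -2.06 ± 0.75; edgeR adjusted p = 0.0505; over its alternatives from 4.39e-08, with only the 6 libraries compared, to 0.285). VGlut was higher in T4, at 28.7 ± 9.7 CPM against 0.573 ± 0.276. Of the 55 optic lobe identity transcription factors, 23 were higher and 6 lower in T4 (24 and 7 adjusted over the list alone, camera adjusted p = 1.18e-05). Of the 8 T4 and T5 transcription factors, 5 were higher in T4 and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 1.05e-05). SoxN stood at 1383 ± 70 CPM against 2.499 ± 0.652 and acj6 at 605 ± 56 against 0.882 ± 0.588, whereas TfAP-2 did not pass the test, at 422 ± 18 against 294 ± 3.6 (log2 0.52 ± 0.33; edgeR adjusted p = 0.244; over its alternatives from 0.000302, with only the 6 libraries compared, to 0.46).

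Of 31 dpr and DIP genes, 18 were higher in T4 and 1 lower (18 and 2 adjusted over the list alone, camera adjusted p = 1.08e-05), and dpr stood at 993 ± 63 CPM against 0.403 ± 0.147. Beat and side genes were higher in T4 in 11 of 21 cases and lower in 6 (camera adjusted p = 0.277), with beat-IIb among the lower ones at 25.7 ± 6.0 CPM against 666 ± 24. GABA and glutamate receptor genes were higher in 9 of 16 cases and lower in 3 (the same counts adjusted over the list alone, camera adjusted p = 0.048, and adjusted p = 0.158 with an estimated correlation). CG8916 stood at 729 ± 65 CPM against 0.801 ± 0.342 and Nmdar2 at 128 ± 18 against 1825 ± 77. Potassium and calcium channel genes were higher in 6 of 19 cases and lower in 5 (6 and 6 adjusted over the list alone, camera adjusted p = 0.0138, and adjusted p = 0.158 with an estimated correlation). In limma on the deposited values the counts were 5 higher and 6 lower, with a median of 0.0496 relative to all genes. The potassium channel gene Sh stood at 3050 ± 332 CPM against 260 ± 12, and eag at 422 ± 18 against 3.63 ± 1.17. Astrocyte and ensheathing glia genes were higher in 7 of 12 cases (7 adjusted over the list alone, camera adjusted p = 0.0134, and adjusted p = 0.325 with an estimated correlation).

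Glycolysis genes were lower in T4 than in Pm2 in 11 of 13 cases (11 adjusted over the list alone, camera adjusted p = 1.18e-05, and adjusted p = 0.173 with an estimated correlation), with Gapdh2 at 884 ± 92 CPM against 1964 ± 3.6 and Eno at 648 ± 55.5 against 1678 ± 66. Heat-shock genes were lower in 9 of 13 cases (9 adjusted over the list alone, camera adjusted p = 1.18e-05, and adjusted p = 0.141 with an estimated correlation), with the chaperone gene Hsp83 at 1542 ± 62 CPM against 3160 ± 120. Ribosomal protein genes were lower in 28 of 86 cases and higher in 1 (24 and 1 adjusted over the list alone, camera adjusted p = 0.00849, and adjusted p = 0.777 with an estimated correlation). Neuropeptide genes (6 higher and 5 lower of 21, 4 and 5 with the stricter filter; camera adjusted p = 0.985) and lipid metabolism genes (3 higher and 4 lower of 16; camera adjusted p = 0.743) were not called as lists. Nplp1 stood at 51.7 ± 14.2 CPM in T4 against 1741 ± 178 and NLaz at 12.2 ± 2.9 against 1284 ± 73.

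Among the largest differences, the GATA factor gene grn stood at 34.7 ± 3.1 CPM in T4 with no count in Pm2, at least 1868-fold higher. The decarboxylase-like gene amd stood at 15.5 ± 0.9 CPM in Pm2 with no count in T4, at least 797-fold lower in T4. edgeR called 3836 of 10528 genes, 1896 higher and 1940 lower in T4, and 2225 of them by at least 2-fold. Scaling by library total gave 2399 higher and 1528 lower. The camera test called 10 lists, of which optic lobe identity transcription factors, T4 and T5 transcription factors and dpr and DIP genes, 3 lists, were called with an estimated correlation.

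Genes above all 3 other populations were sought for each neuron type. In T4 these included CG3492 (2R, 24472712 to 24474226) at 27.2 ± 3.0 CPM, against 0.608 ± 0.288 in Pm2, 0.170 ± 0.151 in neurons and no count in glia. The sodium-proton antiporter gene Nha2 (3R, 22981459 to 22998528) stood at 11.02 ± 2.01 CPM in T4 and 0.222 ± 0.223 in neurons. In Pm2 they included the dynein heavy chain gene CG9492 (Dhc1; 3R, 9651179 to 9674643) at 244 ± 14 CPM, against 0.404 ± 0.570 in neurons, 0.0412 ± 0.0713 in glia and 0.0255 ± 0.0094 in T4. The genes Fst (3R, 9644978 to 9646154), known from recovery after cold, and the gustatory receptor gene Gr64a (3L, 4026769 to 4028600) stood at 4.24 ± 0.87 and 1.64 ± 0.57 CPM in Pm2 and had no count in T4, neurons or glia. Tests in edgeR called 318 T4-enriched genes, 118 of them by at least 2-fold in each contrast and 23 by at least 8-fold. They called 605 Pm2-enriched genes, 289 by at least 2-fold and 78 by at least 8-fold. The T4 count was 188 without T4 replicate 2 and 201 without neurons replicate 3. In limma with library weights on unscaled counts, 884 T4-enriched and 1417 Pm2-enriched genes were called.

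Many genes were called in the same direction in T4 and in Pm2 against the same mixed neurons. Among genes called lower in both were the fly eye-field gene toy, the peptide gene sNPF and the receptor gene Dop2R, which stood at 1.44 ± 0.46 CPM in T4, 0.293 ± 0.163 in Pm2 and 132 ± 9.6 in neurons. Tektin-C and TfAP-2 were called higher in both. In all, 1034 genes were called in the same direction, 330 higher and 704 lower, where independent lists of these sizes would share 449. A further 397 genes were called in opposite directions, 168 higher in T4 and lower in Pm2 and 229 the reverse. Independent lists would give 421 such genes. All 397 were also called between T4 and Pm2. That contrast is the difference of the 2 used to pick them, from the same fit, so these calls are not separate support. Both comparisons use the same 3 neuron libraries, so part of the 1034 shared calls can come from those controls. The neurons are also a mixed population, so genes of other neuron types can be called lower in both comparisons. In 30 simulated sets of unchanged groups that share the controls, edgeR called a mean of 0 genes in both. These sets hold no effects and so do not say how many of the 1034 come from the controls. The correlation of the log2 differences across genes, which are not independent replicates, was 0.431, against a mean of 0.508 in the simulated sets, and the covariance was 2.28, against 0.326.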

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

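The split and grouping tests and the comparison of T4 with Pm2 were planned, and the list of 3 results below was drawn by a rule fixed beforehand. In gene groups of 3 kinds, more genes were called in one direction in T4 and in the other in Pm2, each against the same neurons. The rule also required a camera call in the direct comparison of T4 with Pm2. The camera p-values of that comparison below therefore helped to pick the lists and are not separate support. Against neurons camera called the 3 lists in T4, but in Pm2 only the T4 and T5 transcription factors (camera adjusted p = 0.00015), and not glycolysis genes (camera adjusted p = 0.139) or ribosomal protein genes (camera adjusted p = 0.407). With an estimated correlation these calls against neurons were lost: in T4 adjusted p = 0.161 for the T4 and T5 transcription factors, 0.206 for glycolysis genes and 0.767 for ribosomal protein genes, and in Pm2 0.0624 for the T4 and T5 transcription factors. T4 and T5 transcription factors were higher in 4 of 8 cases in T4 and lower in 6 of 8 in Pm2, and differed between them (camera adjusted p = 1.05e-05, and adjusted p = 0.0447 with an estimated correlation). Glycolysis genes were lower in 9 of 13 cases in T4 and higher in 5 of 13 in Pm2, and differed between them (camera adjusted p = 1.18e-05, and adjusted p = 0.173 with an estimated correlation). Cytoplasmic ribosomal protein genes were lower in 18 of 86 cases in T4 and in Pm2 higher in 7 and lower in 5 (3 higher and 7 lower with scaling by library total, with a median of 0.15 relative to all genes), and differed between them (camera adjusted p = 0.00849, and adjusted p = 0.777 with an estimated correlation).

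The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes called between glia and neurons, 1 of 10 splits gave as many as the real 7236, and the highest other gave 0. For T4 and neurons it was 1 of 10, with 2444 genes against 0, for Pm2 and neurons 1 of 10, with 3749 against 0, and for T4 and Pm2 1 of 10, with 3836 against 2. For lists called by camera, 3 of 10 splits of glia and neurons gave at least the real 17, and the highest other gave 20. The corresponding counts of lists were 14 against 9 for T4 and neurons, 13 against 11 for Pm2 and neurons and 10 against 9 for T4 and Pm2, each reached by 1 of 10 splits. Splits that mixed glia and neurons called 13 to 20 lists with 0 genes called, so the number of lists does not set those populations apart. Every mixed split keeps part of the population difference, since 3 libraries cannot be divided evenly.

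Over 100 groupings of the 12 libraries into 4 groups of 3, the real one among them, 1 gave as many T4-enriched genes as the real 318. The highest other gave 4. For Pm2-enriched genes 2 of 100 reached the real 605, and for calls shared by T4 and Pm2 2 of 100 reached the real 1034. These shares argue against a random order of all 12 libraries. They cannot exclude chance among T4, Pm2 and neurons alone, since the groupings also mix in the glia libraries. The highest others, 1938 and 4576, came from groupings that put the 3 glia libraries together, in the place of Pm2 and of neurons, and so point to the distance of glia from the rest.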

How the results depend on the processing

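Scaling by library total, the counts as deposited without scaling and limma-trend on the deposited values were chosen after seeing the data. Counts of genes and lists not named here stayed within 1.5 times under each alternative run. The cause of the changes below was not tested. The limma settings named below also had no scaling between libraries, so they differ from the main test in scaling as well as in model. Genes called under limma-trend were 488 T4-enriched, 911 Pm2-enriched and 1559 shared on the deposited values (pseudocount 1), and 546, 994 and 1637 with pseudocount 5. With library weights they were 5006 for T4 and 6813 for Pm2 against neurons, 884 T4-enriched, 1417 Pm2-enriched and 3079 shared. A 2-fold threshold, which drops calls by construction, left 1232 for T4 and 2244 for Pm2 against neurons and 2225 for T4 against Pm2. Lists called by fry in one direction were 28 for glia, 22 for T4 and 24 for Pm2 against neurons and 24 for T4 against Pm2; in either direction they were 31, 27, 31 and 31. With an estimated correlation camera called 2, 2 and 3 lists in the last 3 comparisons. List tests with DESeq2 were not run, and the planned TMM scaling and edgeR became the main choices.

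Leaving out 1 library gave 188 (without T4 replicate 2) to 435 (without glia replicate 2) T4-enriched genes, and 201 without neurons replicate 3. It gave 417 to 720 Pm2-enriched genes, and 690 (without neurons replicate 3) to 1343 shared calls. A replicate block for T4 and Pm2 gave 4580 genes and 9 lists. Of 10944 values for 577 named gene results, 10335 kept direction and side of the threshold, 211 gained a call, 6 reversed and the rest lost the call (74 results); DESeq2 gave no adjusted p for 14. The reversed ones were nSyb in Pm2 against neurons, at a log2 difference of 0.0125 as deposited without scaling and 0.0146 in limma-trend on the deposited values with pseudocounts 1, 0.1 and 5 and without a trend (main -0.35; adjusted p over its alternatives 0.000405 to 0.96), and Mhc in T4 against Pm2, at -1.75 without T4 replicate 1 and 6.57 to 8.78 without another library.

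Without scaling, the median of all genes moved by 0.29 in T4, 0.36 in Pm2 and 0.11 in glia against neurons. In the unscaled limma fits it moved by 0.30 in T4 and 0.37 in Pm2 with pseudocount 1. With library weights it moved by 0.32 and 0.39, so most of that shift was present without weights. Quantile normalization moved it by 0.15, 0.15 and 0.14, and median-of-ratios scaling by 0.13 in glia. Scaling by library total moved it by -0.35 in glia and by 0.16 in T4 against Pm2. Without scaling, pan-neuronal genes were higher in 3 and lower in 1 of 18 cases in T4 (main 0 and 3; median 0.05 relative to all genes) and higher in 3 and lower in 0 in Pm2 (main 1 and 6; median -0.10 relative to all genes). Surface glia genes in Pm2 were then higher in 5 and lower in 3 (main 3 and 6; median -0.31 relative to all genes), and channel genes in T4 higher in 4 and lower in 2 (main 2 and 4; median -0.12 relative to all genes), so both lists still lay below the median of all genes. With 3 libraries each, edgeR recovered 4.48% to 11.9% of simulated 1.5-fold changes. Few genes were changed in those simulated sets, so the share recovered in the real comparisons can differ.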

Other observations

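The tests on elav from neuron RNA and paralogs, on VGAT from GABAergic cells, on Hsp70Bb and on neighbouring genes were chosen after the results were seen, as were the names of the other heat-shock genes given with Hsp70Bb. T4 libraries held more transcripts of the amine enzymes Ddc and Tbh than Pm2 libraries. Of 9 monoaminergic genes 2 were higher and 1 lower in T4 than in Pm2, and the list was not called (camera adjusted p = 0.566). Ddc, which encodes dopa decarboxylase, stood at 651 ± 185 CPM in T4 and 20.3 ± 1.3 in Pm2 (log2 5.003 ± 0.728; n = 3 each; edgeR adjusted p = 0.000289), and Tbh, tyramine beta-hydroxylase, at 220 ± 25 against 2.06 ± 0.75 (log2 6.73 ± 0.93; edgeR adjusted p = 0.0002). Against neurons neither passed the test, with Ddc at 603 ± 91 CPM there (edgeR adjusted p = 0.934) and Tbh at 83.7 ± 1.6 (edgeR adjusted p = 0.194), and of 9 monoaminergic genes 3 were lower in T4 than in neurons (camera adjusted p = 0.39). Among these 3 were the vesicular monoamine transporter gene Vmat, at 0.413 ± 0.421 CPM in T4, 0.302 ± 0.491 in Pm2 and 300.2 ± 19.3 in neurons, and the tyrosine hydroxylase gene ple, at 0.370 ± 0.521, 13.99 ± 2.32 and 55.3 ± 8.9. The dosage compensation RNA roX1 stood at 47.3 ± 25.6 CPM in T4, 10.4 ± 1.6 in Pm2, 32.6 ± 2.7 in neurons and 32.5 ± 5.5 in glia, and the cyclic AMP enzyme gene rut at 673 ± 49 CPM in Pm2 against 168 ± 20 in neurons. Of 6 sex-related genes, 3 were higher and 0 lower in T4 than in Pm2 (camera adjusted p = 0.252). In Pm2 against neurons 0 were higher and 2 lower (camera adjusted p = 0.352).

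Some lists were not called in any comparison; between glia and neurons their counts were as follows. Innexin genes were higher in 3 and lower in 1 of 5 cases (camera adjusted p = 0.286), with Inx2 at 1021 ± 270 CPM in glia against 5.01 ± 1.77. Lipid metabolism genes were higher in 8 and lower in 4 of 16 cases (camera adjusted p = 0.0838), and monoaminergic genes higher in 1 and lower in 6 of 9 (camera adjusted p = 0.544). Immediate early genes were higher in 5 and lower in 3 of 8 cases (camera adjusted p = 0.608), with kay at 497 ± 49 CPM against 63.7 ± 6.5 and Hr38 at 8.86 ± 2.30 against 278 ± 86. Haemocyte genes were higher in 3 and lower in 1 of 5 (camera adjusted p = 0.29), fat body genes higher in 2 of 4 (camera adjusted p = 0.478), muscle genes in 4 of 9 (camera adjusted p = 0.478), tracheal genes in 1 of 6 (camera adjusted p = 0.608) and antimicrobial peptide genes in 1 of 4 (camera adjusted p = 0.756). Sex-related genes were higher in 1 and lower in 1 of 6 cases (camera adjusted p = 0.756). Within that comparison neuropeptide genes (1 higher and 15 lower of 21; camera adjusted p = 0.134), glycolysis genes (7 and 1 of 13; camera adjusted p = 0.234), photoreceptor genes (0 and 5 of 13; camera adjusted p = 0.479), heat-shock genes (2 and 6 of 13; camera adjusted p = 0.756) and mitochondrially encoded genes (0 and 0 of 13; camera adjusted p = 0.756) were not called either. Mitochondrially encoded genes were lower in 8 of 13 cases in T4 than in Pm2 (camera adjusted p = 0.0784).

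In the glia libraries elav stood at 21.5 ± 3.8% of its neuron level, against a median of 1.66% over the other 17 pan-neuronal genes. Syx1A, Csp and unc-13 also lay far above that median, at 16.05 ± 0.33%, 14.01 ± 1.70% and 12.2 ± 1.7%, and the remaining 14 at 0.949% to 2.60%. The gene elav was picked because it differed least of the 18. RNA from neurons would bring the others at shares like that of elav. In 3 of 3 glia libraries 14 of the other 17 had at most 3.13%, and elav had at least 18.2%. This argues against it as the whole source of elav RNA. Reads shared with the paralogs fne and Rbp9 are argued against too, since both together had 26.6 ± 6.4 CPM in glia, less than elav in 3 of 3 libraries. Of the genes whose exons overlap elav, 0 were called higher in glia, but 1 of the 2, the long non-coding RNA gene enrr, has no row in the deposited table. The planned bound on called genes assumed a row for each overlapping gene, so it decides nothing, and reads of an overlapping gene cannot be told apart from elav RNA. Transcription of elav in glia stays open beside it and was not tested.

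VGAT stood at 24.0 ± 0.9% of its Pm2 level in T4, and Gad1 at 0.168 ± 0.114%. Low Gad1 was part of what was noticed, so it can argue against an explanation but not for one. Cells with the lowest ratio of Gad1 to VGAT found in a Pm2 or neuron library would bring at least 628 CPM of Gad1 with the VGAT counts of T4. Gad1 reached 37.1 CPM at most in the 3 T4 libraries, which argues against RNA from GABAergic cells with such ratios. No annotated gene overlaps exons of VGAT, so 0 genes met the planned test for overlapping reads. Where the VGAT RNA in T4 comes from stays open, and VGAT transcription in T4 was not tested.

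Hsp70Bb stood at 310.3 CPM in Pm2, 142 in glia, 14.7 in neurons and 1.03 in T4. A heat-shock response would raise most of the other 12 heat-shock genes. Against neurons 2 of the 12 were called higher in Pm2, DnaJ-1 and Hsp83, and 3 lower, which argues against it as the source of the difference from neurons. Against T4, 8 of the 12 were called higher in Pm2 (whole list: camera adjusted p = 1.18e-05, and adjusted p = 0.141 with an estimated correlation), so for the difference from T4 a heat-shock response stays open, as do low levels of these genes in T4, where 12 of the 13 on the list were lower than in neurons. Of the other 5 Hsp70 copies, 0 were called higher in Pm2 than in neurons and 2, Hsp70Ab and Hsp70Bc, lower. Against T4, 1 of the 5, Hsp70Aa, was called higher, and the 5 together had 3.46 ± 0.70 CPM in Pm2. How reads that match several copies were counted is not stated, so low counts of the other copies do not decide whether reads were shared. Hsp70 sequence carried by a transgene cannot be told apart from the gene itself, since counts hold no positions along the gene.

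A further hypothesis was that enriched genes lie side by side in the genome more often than random tested genes. The 599 Pm2-enriched genes with a position formed 73 neighbouring pairs, against a mean of 34.4 and a highest of 54 in 10000 random sets (permutation p = 0.0001, the smallest these can give). The 309 T4-enriched genes formed 39 pairs, against a mean of 9.19 and a highest of 23 (permutation p = 0.0001, the smallest these can give). Co-regulated neighbours would give such counts, but tandem paralogs and genes that overlap, which unstranded libraries do not separate, stay open. Overlap does occur among these genes. CG17738 (3R, 12270890 to 12271300) and Sfp87B (3R, 12273126 to 12273521) lie within the span of svp, and all were Pm2-enriched. How many of the pairs overlap or are tandem paralogs was not tested.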
